A study of Mus musculus with 26 samples.

How the data were processed

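The data are 16S ribosomal RNA gene amplicon profiles of fecal pellets from C57BL/6 mice, an inbred laboratory strain. DNA was extracted with the ZymoBIOMICS DNA Miniprep kit, the V3/V4 part of the gene was amplified by the Illumina 16S protocol, and libraries were read as paired ends on a MiSeq, per the labels' protocols. Mice were given antibiotics (ABX) or vehicle, per the labels. The 26 libraries form 6 groups. The 21-day table holds 3 vehicle and 3 ABX libraries. The table of the fecal microbiota transplant (FMT) holds 20 libraries, 5 in each of 4 groups, from 5 vehicle and 5 ABX mice sampled before and after the transplant. Groups and replicate names were taken from the sample labels, and mice are named by an M and their number there. The titles name day 14 for all pellets taken before FMT, whereas the descriptions name day 12, 13 or 14, and the days of the descriptions were used as a possible batch.

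The authors deposited whole-number read counts per amplicon sequence variant (ASV, a distinct denoised sequence) for each library, and a table that names the taxon of each of 2798 sequences, as the file contents show. The denoiser, its settings, the read filters and the taxonomy database are not given in the sources used here. The counts are not normalized, and the counts of 1 row of the deposited count tables that belongs to no sample were not used. Sequences seen only in that row stayed among the 2798 named ones, from which the FMT sequences were named. The 6 libraries of the 21-day table hold 1429 sequences and the FMT table holds 964. Of the 21-day sequences, 1341 (93.8%), with 98.8% of the reads, still carry both amplification primers. Removing the primers leaves 582 distinct inserts from these, and up to 37 deposited sequences share 1 insert, so ASV richness of that table counts some inserts several times. The FMT sequences carry no forward primer. The 2 tables were therefore never compared with each other.

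The deposited taxon names cover the 21-day sequences. The FMT sequences were named here from the nearest named sequence by edit distance with edlib 1.3.9.post1, after primer removal. Names were given down to genus at 94.5% identity, family at 86.5%, order at 82%, class at 78.5% and phylum at 75%. Without an exact match, a genus name was given only where no sequence of another named genus lay within 1 percentage point of the best match. Exact matches were found for 265 (27.5%) of the 964 sequences, with 5.42–96.6% of the reads of a library. They covered 83.6–96.6% in vehicle libraries before FMT and 31.3–51.3% after it. In ABX libraries they covered 5.42–39.0% before and 37.9–52.1% after FMT. The share of exact matches thus differs between the groups, and changes of unclassified features between them may depend on the naming. Names at family level covered 97.1–100% of the reads of a library and names at genus level 5.53–53.9%, so many genera here are the unclassified remainder of a family. The rule was checked by naming 1044 distinct named inserts from the others. It gave the deposited genus for 429 of 454 inserts that both name (94.5%), the family for 814 of 850 (95.8%) and the phylum for 942 of 950 (99.2%). The check used inserts of the deposited names only and need not hold for sequences farther from them. Reads at 94.5% identity or more made up 43.9–65.8% of the libraries after FMT. The taxon names of the FMT libraries are thus estimates.

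Reads were summed per genus, giving 161 features in the 21-day table and 100 in the FMT table. Genera with at least 10 reads over the libraries of a fit and reads in at least 2 of them were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust dispersion, the library total as the only scaling, and Benjamini-Hochberg adjustment at 0.05. A fold is thus a ratio of mean percent of reads. The fit covered the 6 libraries of the 21-day table (85 genera) or the 4 groups of the FMT table (81 genera), which share 1 dispersion estimate. Log2 fold changes have their standard error (SE). Where all libraries of a group hold 0 reads, a fold is given as "at least", against a floor of 3 reads per library, and a group with 1–3 reads in all is given no fold. Families were tested in the same way. Phylum shares and the summed shares of the taxon lists were compared with a two-sided exact permutation test of the difference of means, adjusted over the phyla or lists of a comparison.

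ASV richness is the expected number of ASVs in 9387 reads (21-day table) or 51118 reads (FMT table), the lowest library totals. The Shannon index uses the natural log. Both were compared by a two-sided exact permutation test over all 20 assignments of 3 against 3 libraries, whose smallest p is 0.1, or all 252 assignments of 5 against 5, whose smallest p is 0.00794. Bray-Curtis distances between ASV shares were tested by PERMANOVA over the same assignments, with R2 as the share of variation between groups. An ASV was counted as one of the vehicle group before FMT where at least 2 of its 5 libraries held at least 3 reads of it. These parts used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

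Genera were named by a fixed rule. It takes, per comparison, the 10 past the threshold with the highest share, the 5 others with the largest fold upward and 5 downward with at least 50 reads, and every measured member of 34 genera that are always named. Families and phyla are the 5 with the highest share, and ASVs the 3 with the highest share per group. The 13 taxon lists were Clostridia families with many butyrate producers, Bacteroidales families, Akkermansiaceae, Enterobacterales families, lactic acid bacteria families, Bifidobacteriaceae, Desulfovibrionaceae, Erysipelotrichales families, Sutterellaceae, segmented filamentous bacteria, Deferribacteraceae, genera known as reagent contaminants, and organelle or unassigned reads. Of these, 10 had a measured member in each table, and Desulfovibrionaceae, segmented filamentous bacteria and Deferribacteraceae had 0 ASVs in either. The groups, the comparisons, the tests, the lists, the naming rule and most alternative settings were fixed before the data were examined. The matching of FMT sequences to named ones, the identity limits and the alternatives named as added in the closing part were chosen afterwards.

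The FMT libraries are paired because the labels give the same mouse numbers before and after. Deviations of a mouse's libraries from their group means had correlations of -0.418 to 0.440, and the own mouse gave the highest of the 5 correlations in 2 of 10 mice. The main tests leave out this pairing and a fit with the mouse as a block was run as an alternative. With 5 pairs, the exact test over 32 sign flips cannot go below p = 0.0625. Mice were cohoused after a washout and received FMT by gavage, per the labels' protocols, so libraries after FMT are not independent of cage mates. The labels of the 21-day libraries give replicate codes and do not say whether these are separate mice. Vehicle libraries 1 and 2 share the code part YC1 and ABX libraries 2 and 3 share YA2, whose meaning is not given. ABX libraries 2 and 3 lay at a Bray-Curtis distance of 0.280, against 0.746 and 0.737 to ABX library 1. Vehicle libraries 1 and 2 lay 0.627 apart, and 2 and 3 lay 0.480 apart. The 21-day tests treat libraries as independent, so their p-values measure only the spread between these samples. A chi-square comparison of counts found 0 pairs of libraries within sampling noise, with a lowest chi-square per degree of freedom of 23.0 in the 21-day table and 12.0 in the FMT table.

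Shares of reads are relative, so other scalings were run as alternatives: TMM factors of edgeR, DESeq2 1.42.0 with poscounts size factors, and limma 3.58.1 on centred log ratios with 0.5 reads added. Against the main setting they moved the median log2 fold change of all genera by 2.30, 0.24 and -1.14 for ABX against vehicle at 21 days, by 0.17, 1.03 and 1.95 before FMT, by 0.19, -0.73 and -2.03 for ABX after against before FMT, by 0.12, 0.03 and 0.12 for ABX against vehicle after FMT, by 0.28, 0.16 and -0.12 for vehicle after against before, and by 0.40, 0.21 and -0.02 for ABX after against vehicle before. Folds in the text are relative to the library total. Other alternatives changed the filter, the feature level, the groups in the fit, the test, the distance, the treatment of organelle reads and primers, the identity for names, the sampling day or mouse as a block, and left out each library in turn.

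The genus test was run on simulated counts drawn from the means and totals of these libraries, in 10 sets with 20 changed genera each, 10 per fold. At the dispersion of the 21-day libraries (median 3.84) it recovered 0% of 16-fold and 2% of 1024-fold changes, and at a dispersion of 1, a value chosen after the first run, 45% and 100%. In the FMT table (median 1.20), 4-fold and 16-fold changes were recovered in 36% and 85% for ABX against vehicle before FMT, 15% and 84% for ABX after against before, 28% and 82% for ABX against vehicle after FMT, 20% and 87% for vehicle after against before, and 24% and 91% for ABX after against vehicle before. This recovery need not hold for each taxon. The family Acholeplasmataceae was 23.3-fold higher in vehicle mice after than before FMT and was not called (edgeR adjusted p = 0.172). A taxon that did not pass may thus still differ by more than 16-fold. Library totals were 9387–67616 reads in the 21-day table and 51118–76806 in the FMT table. A count of 0 allows a share of up to 0.00391–0.0320%, depending on the library. Shares of 1 library are given with 95% Wilson intervals. Reads of a PCR without molecular identifiers are not independent molecules, so intervals and these limits cover counting error only.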

Results

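Fecal bacteria were profiled by 16S amplicon sequencing in mice given vehicle or antibiotics, to follow depletion of the gut microbiota and its refilling by FMT in a study of gut dysbiosis and brain metastasis. Pellets of 1 experiment were taken after 21 days of treatment (3 vehicle and 3 ABX libraries). In the other, mice were pre-treated for 14 days, left on plain water for 2 days, randomized and cohoused, and all were then gavaged over 7 days with pellet supernatant from vehicle pre-treated mice. Its pellets came from 5 vehicle and 5 ABX mice before and after FMT. No group went without FMT, so its effect cannot be told apart from those of the end of treatment, cohousing and time. Library totals were 38242–67616 reads in the 21-day vehicle group and 9387–21771 in the 21-day ABX group. They were 63137–76588 in the vehicle group before FMT, 66082–73640 in the ABX group before FMT, 51118–74026 in the vehicle group after FMT and 58707–76806 in the ABX group after FMT. Values are percent of reads as mean ± SD with n = 3 libraries per 21-day group and n = 5 per FMT group, unless a range is given. Adjusted p-values of genera and families are those of the edgeR quasi-likelihood test.

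The comparison at 21 days asks what antibiotics did to the fecal community. Reads named as mitochondria or chloroplast made up 24.7–79.7% of the ABX libraries and 0.0261–0.0841% of the vehicle libraries. Mitochondrial sequences made up 51.5 ± 26.2% of ABX reads against 0.0599 ± 0.0301% of vehicle reads, 860-fold higher (log2 fold change 9.74, SE 1.36, adjusted p = 4.34e-10), and chloroplast sequences 6.99 ± 3.50% against 0 reads, at least 1108-fold higher (adjusted p = 9.77e-05). Bacteroides, a gut genus that degrades polysaccharides, held 0.251 ± 0.264% of ABX reads against 38.1 ± 36.0%, 152-fold lower (log2 fold change -7.25, SE 1.36, adjusted p = 7.55e-06). Akkermansia, which degrades mucin, held 0.200 ± 0.122% against 15.2 ± 7.61%, 76.1-fold lower (adjusted p = 0.00988). Each of these 4 genus-level features, organelle sequences included, had the same direction in all 3 libraries of each group.

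Of 85 genera tested at 21 days, those 4 passed the threshold, 2 higher (both organelle sequences) and 2 lower, and 52 had an unadjusted p under 0.05. Single libraries differed widely within each group. Vehicle library 1 held 79.6% Bacteroides (Wilson interval 79.3–79.9%) and 18.4% Akkermansia (18.1–18.7%), and ABX library 1 held 63% Ralstonia (62.4–63.6%), a genus known from water and reagents, with 0 Ralstonia reads in ABX libraries 2 and 3 and 0.0628–0.296% in the vehicle libraries. The count of genera was 34 with TMM factors (33 higher, 1 lower), 30 with DESeq2 (23 and 7) and 41 with limma on centred log ratios (19 and 22). Of the 4 genera, 3 stayed called with TMM factors, 2 with DESeq2 and 4 with centred log ratios. Akkermansia had an adjusted p of 0.0614 with TMM factors, and DESeq2 gave none for Akkermansia and Bacteroides. It was 20 without ABX library 1, 24 without ABX library 2, 60 without vehicle library 1 (26 higher, 34 lower), 10 without vehicle library 2 and 27 without vehicle library 3. Akkermansia had an adjusted p of 0.110 without ABX library 3, and 0 genera passed once organelle reads were removed. The log2 fold change of Bacteroides was then -5.44 (SE 2.04, adjusted p = 0.0636), from -7.25 (SE 1.36), and that of Akkermansia -4.40 (SE 2.39, 0.129), from -6.25 (SE 1.77).

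Other gut genera did not pass the threshold at 21 days. Lactobacillus, a lactic acid producer, held 6.83 ± 2.82% of ABX and 2.27 ± 1.82% of vehicle reads (adjusted p = 0.390). Alistipes held 0.0710 ± 0.123% and 4.80 ± 5.41% (adjusted p = 0.0594), the Lachnospiraceae NK4A136 group 0.115 ± 0.0480% and 2.25 ± 2.50% (adjusted p = 0.209), and Bifidobacterium 0.126 ± 0.155% and 1.98 ± 3.41% (adjusted p = 0.243). Oscillibacter and Roseburia, both of the Clostridia, had 0 reads in the ABX libraries against 0.404 ± 0.354% (at least 19.7-fold, adjusted p = 0.0685) and 0.245 ± 0.241% (at least 12.0-fold, adjusted p = 0.0693). Parasutterella held 0.00710% (2 reads) against 0.413 ± 0.283% (adjusted p = 0.176). Streptococcus held 0.576 ± 0.531% against 2 reads (adjusted p = 0.0944) and Lactococcus 0.0750 ± 0.0543% against 0 (at least 11.9-fold, adjusted p = 0.0561). Enterococcus held 1.45 ± 2.32% against 0.538 ± 0.292% (adjusted p = 0.638), a direction that turned with DESeq2 and centred log ratios and came from ABX library 1 with 4.12% (3.87–4.40%). Turicibacter held 0.629 ± 0.655% against 4.54 ± 7.86% (adjusted p = 0.241), a direction that turned with TMM factors and centred log ratios. Its vehicle reads lay in vehicle library 3 (13.6%, 13.3–13.9%), without which its log2 fold change was 10.62 with an adjusted p of 0.0456. Dubosiella was too rare to test.

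At family level, Muribaculaceae, the main Bacteroidales family of the mouse gut, made up 0.612 ± 0.764% of ABX reads against 15 ± 13.1% of vehicle reads, 24.5-fold lower (adjusted p = 0.0278). Bacteroidaceae (adjusted p = 0.000178) and Akkermansiaceae (0.0156) were lower and Mitochondria (1.76e-07) higher, with the shares of their genera above. Burkholderiaceae held 21.0 ± 36.4% against 0.148 ± 0.129% (adjusted p = 0.154), all from Ralstonia in ABX library 1, and the direction turned with centred log ratios. Among phyla, Proteobacteria, to which the naming assigns mitochondria, made up 74.2 ± 10% of ABX and 0.627 ± 0.136% of vehicle reads. Bacteroidota made up 0.934 ± 1.15% and 57.8 ± 20.2%, Verrucomicrobiota 0.200% and 15.2%, and Cyanobacteria, which hold chloroplasts, 6.99% and 0%, each with exact permutation p = 0.1, the smallest that 3 against 3 allows (adjusted p = 0.160). Firmicutes made up 14.1 ± 4.58% and 23.8 ± 22.1% (exact permutation p = 0.6, adjusted p = 0.8). The leading ASVs of the vehicle group were Bacteroides at 1.98, 1.83 and 1.71%, and those of the ABX group mitochondrial at 4.58, 4.11 and 3.96%. Sequences that differ only in primer ends count as separate ASVs here, so each value may be a part of the share of its insert.

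Among the taxon lists at 21 days, none of 10 could pass, since the smallest adjusted p was 0.167 by the exact permutation test. Clostridia families with many butyrate producers held 0.328 ± 0.215% in ABX and 12.3 ± 10.7% in vehicle libraries, and 0 of 21 genera passed over all genera and 0 when adjusted over the list alone. Bacteroidales families held 0.934 ± 1.15% and 57.8 ± 20.2%, with 1 of 3 genera lower and 3 when adjusted over the list alone. Akkermansiaceae had 1 of 1 lower both ways. The lactic acid bacteria families held 9.44 ± 1.51% and 2.82 ± 1.53%, with 0 of 8 genera past and 5 higher when adjusted over the list alone. Enterobacterales families, here Erwiniaceae, held 0.124 ± 0.148% and 0%, with 0 of 1 past and 1 higher when adjusted over the list alone. Bifidobacteriaceae (0.126% and 1.98%), Erysipelotrichales families (0.658 ± 0.704% and 5.08 ± 8.01%) and Sutterellaceae (0.00710% and 0.413%) had 0 members past, also when adjusted over the list alone. Genera known as reagent contaminants held 23.7 ± 35.0% and 0.200 ± 0.150%, with 0 of 8 past and 5 higher when adjusted over the list alone. Organelle or unassigned reads held 58.5 ± 29.7% and 0.0621 ± 0.0329%, with 2 of 2 higher both ways. Of the always-named genera tested, 2 of 13 were lower, and 2 lower and 1 higher when adjusted over the list alone.

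**Figure D1:**
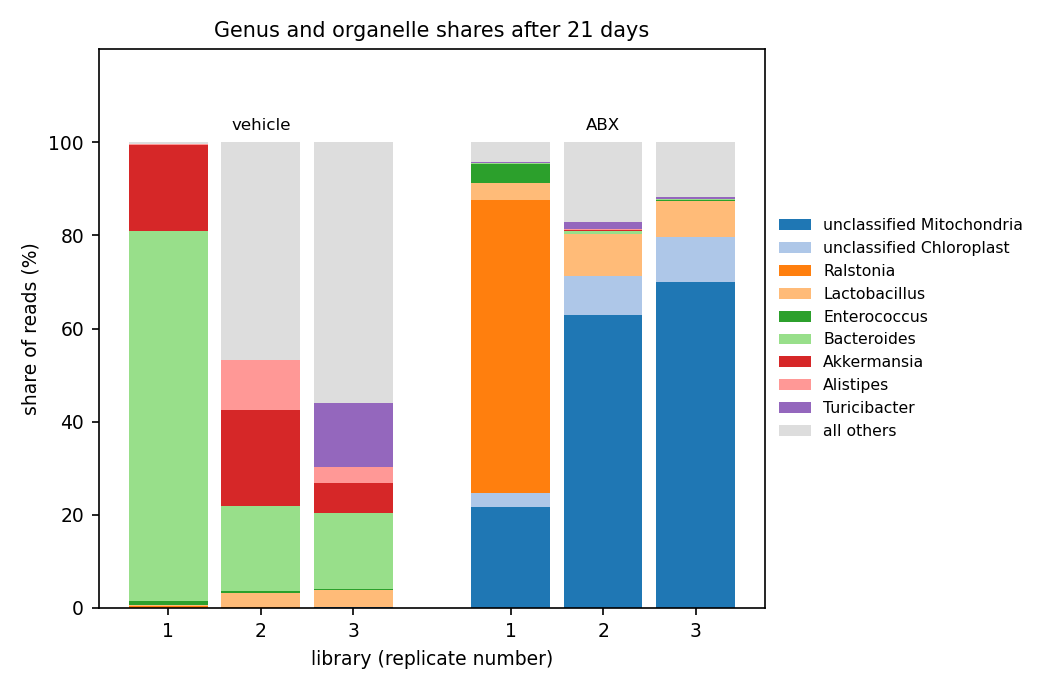
Stacked bars of the percent of reads per library at 21 days, 1 bar for each of 3 vehicle and 3 ABX libraries, with colours for 9 named genera and organelles and gray for all others. Mitochondrial reads reach 21.6–70.0% in the ABX libraries against 0.0261–0.0841% in the vehicle libraries, and Bacteroides lies at 0.0735–0.554% against 16.3–79.6%.

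Diversity of the 21-day libraries overlapped between the groups. ABX libraries held 220 ± 33.5 ASVs in 9387 reads and vehicle libraries 397 ± 268 (difference -177, exact permutation p = 0.4), and the Shannon index was 4.43 ± 0.10 against 5.12 ± 1.06 (exact permutation p = 0.4). Bray-Curtis distances between the groups averaged 0.984, and group accounted for an R2 of 0.570 (exact permutation p = 0.1, the smallest that 3 against 3 allows). Deposited sequences that differ in primer ends count as separate ASVs in these numbers, and organelle sequences count as ASVs too. Without organelle and unassigned reads, richness in 2703 reads was 131–180 in the ABX and 83.2–512 in the vehicle libraries. With primers removed and identical inserts merged, the richness difference was -3.92 (exact permutation p = 1), the Shannon difference -0.63 (0.5) and R2 0.601 (0.1). The richness difference was -327 without vehicle library 1 and -67.2 without vehicle library 3, and the Shannon difference -1.30 and -0.29.

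Before FMT, the comparison of ABX with vehicle mice shows the state late in the pre-treatment. By their labels, these pellets came before the washout and the cohousing. The state at the first gavage was not sampled. Reads of Enterobacteriaceae, a family of facultative anaerobes that holds Escherichia, made up 70.1 ± 39.5% of ABX reads against 0.0509 ± 0.00713% of vehicle reads, 1375-fold higher (adjusted p = 0.000534). Nearly all were of its unclassified genus, 69.9 ± 39.5% against 0.00546 ± 0.00749% (log2 fold change 13.60, SE 2.97, adjusted p = 0.000430). That genus made up 80.4–94.45% of the libraries of ABX mice M141, M159, M139 and M146. The library labelled ABX mouse M149 before FMT stood apart, with 0.0319% of that genus and 0.126% Enterobacteriaceae in all (Wilson interval 0.102–0.156%). The leading ASVs of the ABX group were a pair of Enterobacteriaceae sequences at 42.7 ± 24.1% and 27.3 ± 15.4% and a Parasutterella sequence at 8.08 ± 6.54%. Those of the vehicle group were a pair of Muribaculaceae sequences at 24.6 ± 5.71% and 9.56 ± 1.58% and an Akkermansia sequence at 11.4 ± 6.37%.

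Of the genera past the threshold before FMT, 16 were lower in ABX mice. Bifidobacterium, which ferments plant and host sugars, held 0.0119 ± 0.0266% against 2.69 ± 1.27%, 226-fold lower (adjusted p = 0.0123, and 6.07e-08 without mouse M149). Dubosiella, an Erysipelotrichaceae genus of the mouse gut, held 0.0783 ± 0.173% against 9.06 ± 12.5%, 116-fold lower (adjusted p = 0.0224), with 19.3% (19.0–19.6%) in vehicle mouse M140 and 25.8% (25.5–26.1%) in vehicle mouse M156. Ruminococcus had 0 reads against 0.299 ± 0.373% (at least 68.8-fold, adjusted p = 0.00105) and the Eubacterium nodatum group 0 against 0.130 ± 0.0758% (at least 29.9-fold, adjusted p = 0.00171). Romboutsia had 2 reads in ABX libraries against 0.640 ± 0.499% (adjusted p = 0.00171). The Eubacterium xylanophilum group was 249-fold lower (adjusted p = 0.00796), the Eubacterium ventriosum group 62.5-fold (0.0257) and Defluviitaleaceae UCG-011 68.9-fold (0.0253). The Eubacterium brachy group had 0 reads against 0.0194% (at least 4.48-fold, adjusted p = 0.0123), with -1.90 in DESeq2 (0.638) and -0.76 on centred log ratios (0.653). Monoglobus had 2 reads against 0.0487% (0.0224), with -3.01 (0.246) and -0.92 (0.442) in these, and unclassified Christensenellaceae 0 against 0.0157% (at least 3.61-fold, 0.0142), with -1.47 (0.697) and 0.19 (0.885). Erysipelatoclostridium was 32.9-fold lower (adjusted p = 0.0464), a call lost with adjusted p = 0.0613–0.0859 when any library but that of mouse M149 was left out. All ABX reads of Bifidobacterium (41), Erysipelatoclostridium (79), the Eubacterium ventriosum group (25), Defluviitaleaceae UCG-011 (5), Romboutsia (2) and Monoglobus (2) lay in the library of mouse M149. Dubosiella held 0.387% (0.344–0.436%) there and 0–0.00407% in the other 4. With only these 2 groups in the fit the calls ended for Bifidobacterium (adjusted p = 0.0682), Dubosiella (0.170), the Eubacterium ventriosum group (0.116), Defluviitaleaceae UCG-011 (0.0700) and Erysipelatoclostridium (0.209). On centred log ratios they ended for Dubosiella (log2 difference -3.46, 0.0516) and Defluviitaleaceae UCG-011 (-1.53, 0.212), and with no filter for Erysipelatoclostridium (0.0630).

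Of 81 genera, 20 passed before FMT, 4 higher and 16 lower in ABX mice, and 27 had an unadjusted p under 0.05. Of the higher ones, unclassified Rikenellaceae (0.806 ± 1.80% against 0.01%, adjusted p = 0.0262) and unclassified Bacteroidia (0.0519% against 0 reads, at least 12.0-fold, adjusted p = 0.00796) and Parvibacter (19 against 0 reads, adjusted p = 0.0395) had their ABX reads in the library of mouse M149 alone. Without it unclassified Rikenellaceae was lower in ABX mice (log2 fold change -5.79, adjusted p = 0.00102), and the values of Bacteroidia and Parvibacter were 0 (adjusted p = 1). With day as a block unclassified Rikenellaceae was at -2.44 (0.347), and with only these 2 groups in the fit at 6.30 (0.218). Parvibacter had an adjusted p of 0.0728–0.0929 without any 1 of the 5 vehicle libraries. Unclassified Rikenellaceae had an adjusted p of 0.0501–0.0729 without vehicle mouse M151, M161, M140 or M156. The whole family Rikenellaceae held 0.888 ± 1.98% in ABX and 1.15 ± 0.860% in vehicle mice (adjusted p = 0.839). That direction turned with TMM factors and DESeq2. The count was 61 without mouse M149 (2 higher, 59 lower), 13 without vehicle mouse M161, and 53 with sampling day as a block (1 higher, 52 lower). It was 19 with TMM factors (6 and 13), 23 with DESeq2 (6 and 17), and 46 with centred log ratios (22 and 24), which kept 16, 13 and 11 of the 20, and 11 with only these 2 groups in the fit, all among the 20.

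Several abundant genera had their call decided by the library of mouse M149. Akkermansia held 1.92 ± 4.27% of ABX and 11.4 ± 6.38% of vehicle reads (adjusted p = 0.336, and 1.18e-09 without mouse M149). Bacteroides held 1.17 ± 2.61% and 2.32 ± 0.910% (0.787, and 1.18e-09 without), Turicibacter 0.153 ± 0.326% and 3.22 ± 1.15% (0.105, and 1.98e-06 without), and the Lachnospiraceae NK4A136 group 0.383 ± 0.854% and 2.77 ± 1.57% (0.282, and 5.45e-08 without). Alistipes held 0.0821% and 1.14% (0.148, and 1.05e-06 without), Oscillibacter 0.362% and 0.608% (0.882, and 1.14e-06 without) and Roseburia 0.0989% and 0.380% (0.450, and 3.98e-05 without). Parasutterella, a genus of the Sutterellaceae, held 9.93 ± 8.03% and 0.863 ± 0.621% (0.178, and 0.000128 without). With sampling day as a block, the adjusted p was 0.00185 for Akkermansia, 0.00182 for Bacteroides and Roseburia, 0.00600 for Turicibacter, 0.00249 for the Lachnospiraceae NK4A136 group, 0.00429 for Alistipes and 0.00203 for Oscillibacter, each lower in ABX mice. Lactobacillus held 2.19 ± 4.89% and 0.705 ± 1.03% (adjusted p = 0.571), a direction that turned with centred log ratios. Its log2 fold change was 1.63, and -8.45 without mouse M149 (adjusted p = 1.16e-05). Enterococcus held 0.0184% and 0.0707% (adjusted p = 0.450), a direction that turned with DESeq2 and centred log ratios, and Anaeroplasma 0.0151% and 0.00770% (adjusted p = 0.787, log2 fold change 0.95, and -2.62 without mouse M149). Among families, Erysipelotrichaceae was 47.0-fold lower in ABX mice (0.263 ± 0.569% against 12.3 ± 11.9%, adjusted p = 0.0274). Muribaculaceae held 6.96 ± 15.6% and 45.6 ± 9.0% (adjusted p = 0.174) and Lachnospiraceae 3.65 ± 8.15% and 8.74 ± 3.75% (0.563). The ABX means of these 3 families come from mouse M149, with 1.28% (1.20–1.37%), 34.8% (34.4–35.1%) and 18.2% (17.9–18.5%) there against at most 0.0122%, 0.0118% and 0.00720% in the other 4 libraries, and families were not refitted without it.

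By taxon list before FMT, 3 of 9 lists passed, and 7 without mouse M149. Enterobacterales families (70.1% against 0.0509%), Bifidobacteriaceae (0.0119% against 2.69%) and Erysipelotrichales families (0.291 ± 0.632% against 13.1 ± 12.2%) each had exact permutation p = 0.00794, the smallest possible (adjusted p = 0.0238), and the last 2 were lower in all 5 ABX libraries than in any vehicle library. Bacteroidales families held 9.02 ± 20.2% against 49.0 ± 9.18% (exact permutation, adjusted p = 0.0536), Akkermansiaceae had an adjusted p of 0.0571, Sutterellaceae 0.0714, Clostridia families 0.224 (5.60 ± 12.5% against 14.9 ± 7.03%) and lactic acid bacteria 1 (2.21 ± 4.88% against 0.778 ± 1.04%). Of 29 genera of the Clostridia list, 3 were lower, 3 also when adjusted over the list alone, and 28 without mouse M149. Of 6 Erysipelotrichales genera, 3 were lower and 4 when adjusted over the list alone, and 6 without mouse M149. Of 5 Bacteroidales genera, 1 was higher both ways, and 4 were lower without mouse M149. Of 3 Enterobacterales genera 1 was higher and of 2 Bifidobacteriaceae 1 lower, also when adjusted over the list alone. Of the always-named genera, 3 of 15 were lower both ways, and 11 lower and 1 higher without mouse M149. The other lists had 0 members past, also when adjusted over the list alone. Actinobacteriota, the phylum of Bifidobacterium, held 0.0981% against 2.98% (exact permutation, adjusted p = 0.0476). Proteobacteria (80 ± 44.6% against 0.914%), Bacteroidota (9.07% against 49.0%), Firmicutes (8.91% against 35.6%) and Verrucomicrobiota each had an adjusted p of 0.0571.

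Rarefied richness before FMT was 76.4 ± 139.4 ASVs in ABX and 219 ± 34.1 in vehicle mice (difference -143, exact permutation p = 0.0476). ABX mice M141, M159, M139 and M146 had 12.9–15.8 ASVs and a Shannon index of 0.88–1.14, and the library of mouse M149 had 326 ASVs and an index of 4.33. Without mouse M149 the richness difference was -205 (exact permutation p = 0.00794), and without any other ABX or vehicle library p was 0.0794–0.111. The Shannon index was 1.68 ± 1.48 against 2.94 ± 0.33 (difference -1.26, exact permutation p = 0.0794), with -1.92 and p = 0.00794 without mouse M149. Bray-Curtis R2 was 0.619 (exact permutation p = 0.00794, the smallest possible), and 0.886 without mouse M149. Within sampling days, richness was 14.4 in the 2 ABX against 236 in the 1 vehicle library on day 12, 326 against 235 with 1 library each on day 13, and 13.7 in 2 against 209 in 3 on day 14. The Shannon index was 0.99 against 3.29 on day 12, 4.33 against 2.91 on day 13 and 1.04 against 2.84 on day 14, so day 13, which holds mouse M149, had the opposite order.

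**Figure D2:**
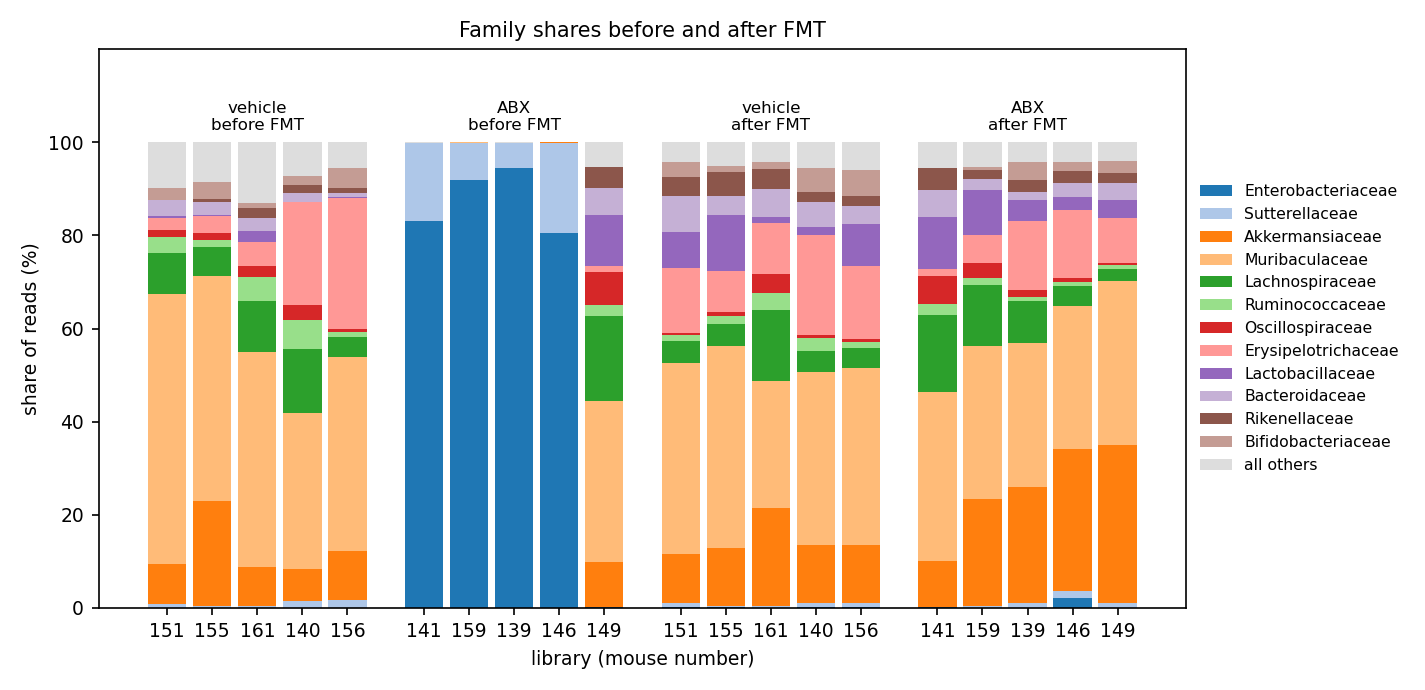
Stacked bars of the percent of reads per library, 1 bar for each of 5 mice in the vehicle and ABX groups before and after FMT, with colours for 12 families and gray for all others. Enterobacteriaceae lie at 80.5–94.6% in 4 ABX libraries before FMT, 0.126% in that of mouse M149, and 0.0445–2.04% in the ABX libraries after FMT.

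After FMT, ABX mice were compared with the same group before it. Unclassified Enterobacteriaceae fell to 0.0466 ± 0.0862% from 69.9 ± 39.5%, 1500-fold lower (log2 fold change -10.55, SE 2.68, adjusted p = 0.00366). Unclassified Erysipelotrichaceae rose to 5.69 ± 4.57% from 0.0313 ± 0.0700%, 182-fold higher (adjusted p = 0.0259), though its leading ASV has 86.9% identity to the nearest named sequence, just over the limit for a family name. Bifidobacterium rose to 1.78 ± 1.48% from 0.0119%, 150-fold higher (adjusted p = 0.0259). Before FMT their reads, 108 and 41, lay in the library of mouse M149 alone. Ruminococcus rose to 0.175 ± 0.229% from 0 reads (at least 40.2-fold, adjusted p = 0.00366), the Eubacterium nodatum group to 0.0314 ± 0.0120% from 0 (at least 7.23-fold, 0.0212), and the Eubacterium xylanophilum group to 0.215 ± 0.220%, 106-fold higher (0.0259). The Eubacterium brachy group (0.0162 ± 0.0274%, at least 3.74-fold, adjusted p = 0.0259) and unclassified Christensenellaceae (0.0111 ± 0.0179%, at least 2.56-fold, 0.0281) were higher than 0 reads, and on centred log ratios their differences turned to -1.24 and -1.47.

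Of 81 genera, 8 passed, 7 higher and 1 lower after FMT, and 17 had an unadjusted p under 0.05. The count was 60 without mouse M149 before FMT (58 higher, 2 lower) and 47 with the mouse as a block (46 higher, 1 lower). It was 10 with TMM factors (9 and 1), 14 with DESeq2 (11 and 3), 50 with centred log ratios (26 and 24), which kept 8, 6 and 3 of the 8, and 0 with only these 2 groups in the fit (adjusted p = 0.0761–0.245 for the 8). It was also 0 by the exact rank-sum test, in which at least 13 genera have to reach the smallest possible p for any to pass. With stricter identity for names, 6 of the 8 stayed called. Unclassified Erysipelotrichaceae then had a log2 fold change of 2.27 (SE 1.73, adjusted p = 0.446) and Christensenellaceae 3.90 (SE 1.82, 0.225). DESeq2 gave 1.49 for the Eubacterium brachy group (0.689) and 1.64 for Christensenellaceae (0.659). Centred log ratios gave 1.21 for Ruminococcus (0.436), 1.46 for the Eubacterium nodatum group (0.209) and 2.11 for the Eubacterium xylanophilum group (0.0654). Single libraries ended calls for Bifidobacterium (adjusted p = 0.0576 without ABX mouse M139 after FMT), the Eubacterium xylanophilum group (0.0549 without mouse M159 and 0.0582 without mouse M139 after FMT), the Eubacterium brachy group (0.146 without mouse M159 after FMT) and unclassified Christensenellaceae (0.0640–0.194 without mouse M141, M159, M139 or M146 before FMT or mouse M146 after FMT).

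Akkermansia and the genera that follow did not pass with all libraries. Akkermansia held 24.4 ± 9.27% after and 1.92 ± 4.27% before FMT (adjusted p = 0.231, and 5.20e-10 without mouse M149 before FMT). Lactobacillus held 6.47 ± 3.65% and 2.19 ± 4.89% (0.600, and 6.24e-07 without), Bacteroides 3.31 ± 1.65% and 1.17 ± 2.61% (0.605, and 6.13e-10 without), Dubosiella 2.50 ± 1.71% and 0.0783% (0.149, and 6.21e-05 without), and Parasutterella 0.804 ± 0.625% and 9.93 ± 8.03% (0.231, and 9.72e-05 without). The Lachnospiraceae NK4A136 group held 1.91% and 0.383% (0.451, and 9.90e-08 without) and Turicibacter 1.06% and 0.153% (0.337, and 1.21e-05 without). Alistipes (0.716% and 0.0821%, 1.80e-06), Oscillibacter (0.535% and 0.362%, 1.17e-06) and Roseburia (0.475% and 0.0989%, 3.02e-05) also had the adjusted p in parentheses only without mouse M149, and 0.284, 0.813 and 0.433 with it. With the mouse as a block, the adjusted p was 0.000605 for Akkermansia and Bacteroides, 0.000931 for Lactobacillus, 0.000879 for Dubosiella, 0.00147 for the Lachnospiraceae NK4A136 group and Oscillibacter, 0.00160 for Alistipes, 0.00232 for Roseburia and 0.0145 for Turicibacter, each higher after FMT, and 0.0591 for unclassified Christensenellaceae. Enterococcus held 0.147 ± 0.320% and 0.0184% (adjusted p = 0.289) and Escherichia-Shigella 7 and 0 reads (0.231), and their directions turned with DESeq2 and centred log ratios. Anaeroplasma held 0.0452% and 0.0151% (0.600, and 0.0163 without mouse M149), a direction that turned with centred log ratios. Among families, Enterobacteriaceae was 152-fold lower after FMT (0.461 ± 0.886% against 70.1 ± 39.5%, adjusted p = 0.0242), with 2.04% (1.94–2.15%) in mouse M146. Muribaculaceae held 33.2 ± 2.56% and 6.96 ± 15.6% (0.338), Akkermansiaceae 0.191 by adjusted p, and Lachnospiraceae 9.12 ± 5.93% and 3.65 ± 8.15% (0.574), with the before values set by mouse M149.

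By taxon list, 4 of 10 passed the exact permutation test after against before FMT in ABX mice. Akkermansiaceae, Bifidobacteriaceae and Erysipelotrichales families (9.45 ± 5.71% against 0.291 ± 0.632%) rose (adjusted p = 0.0265), and Enterobacterales families fell (0.0397). Bacteroidales families held 39.3 ± 4.80% and 9.02 ± 20.2% (exact permutation, adjusted p = 0.0794), Sutterellaceae had 0.0794, lactic acid bacteria 0.193 (6.62 ± 3.48% and 2.21 ± 4.88%), Clostridia families 0.317 (13.4 ± 8.50% and 5.60 ± 12.5%), reagent genera 0.494 and organelle reads 1. The number of lists was 7 without mouse M149 before FMT, 3 without mouse M141 after FMT and 0 with mice paired (exact, adjusted p = 0.156 for each of the 4). Of 29 Clostridia genera 2 were higher, 2 when adjusted over the list alone and 27 without mouse M149. Of 6 Erysipelotrichales genera 1 was higher both ways and 5 without mouse M149. Of 5 Bacteroidales genera 0 passed, also when adjusted over the list alone, and 4 were higher without mouse M149. Of 15 always-named genera 2 were higher, 2 when adjusted over the list alone, and 12 higher and 1 lower without mouse M149. Actinobacteriota (2.96 ± 1.87% against 0.0981%) and Verrucomicrobiota (24.4% against 1.92%) rose by the exact permutation test (adjusted p = 0.0238), and Proteobacteria (1.27% against 80%), Bacteroidota (39.5% against 9.07%) and Firmicutes (31.9% against 8.91%) had an adjusted p of 0.0571.

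Richness of ABX mice was 254 ± 47.1 ASVs after FMT against 76.4 ± 139.4 before (difference 177, exact permutation p = 0.0397), and the Shannon index 3.66 ± 0.45 against 1.68 ± 1.48 (difference 1.98, exact permutation p = 0.0397). With mice paired both had exact p = 0.125. Without mouse M149 before FMT the differences were 240 and 2.64 (exact permutation p = 0.00794), and without mouse M141, M159, M139 or M146 before FMT p was 0.0873 for richness and 0.0794 for Shannon. Bray-Curtis R2 was 0.589 (exact permutation p = 0.0159, paired 0.063). Mean distance to the vehicle libraries before FMT went from 0.946 ± 0.101 to 0.745 ± 0.0143 (difference -0.201, exact permutation p = 0.00794, the smallest possible, paired 0.063). Reads in ASVs of the vehicle group before FMT rose from 23.0 ± 24.4% to 71.7 ± 4.95% (difference 48.7 percentage points, exact permutation p = 0.0159, paired 0.063).

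**Figure D3:**
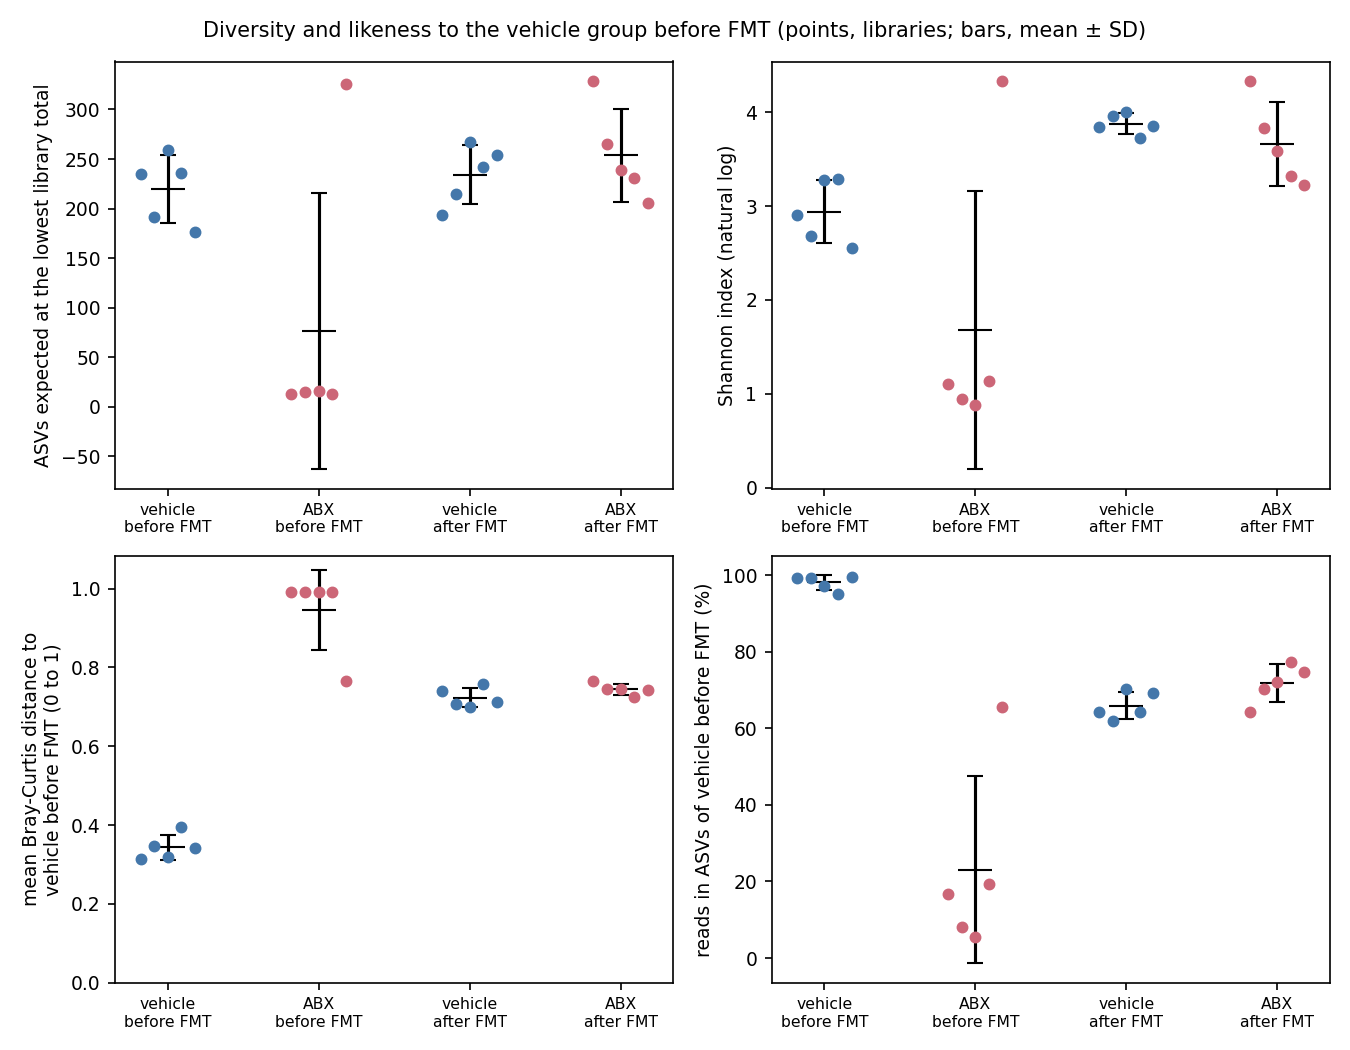
Rarefied ASV richness, Shannon index, mean Bray-Curtis distance to the vehicle group before FMT (0 to 1) and percent of reads in ASVs of that group, with a point per library, 5 per group, and bars for mean and SD. ABX libraries hold 12.9–15.8 ASVs in 4 mice and 326 in mouse M149 before FMT, and 205–329 after it.

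After FMT, ABX and vehicle mice were compared with each other. Akkermansia held 24.4 ± 9.27% in ABX and 13.8 ± 4.17% in vehicle mice, Bacteroides 3.31 ± 1.65% and 5.42 ± 1.54%, Dubosiella 2.50 ± 1.71% and 4.34 ± 2.03%, and Bifidobacterium 1.78 ± 1.48% and 3.32 ± 2.06%. Lactobacillus held 6.47 ± 3.65% and 6.34 ± 4.61%, a direction that turned with TMM factors and DESeq2. Ruminococcus held 0.175 ± 0.229% and 0.474 ± 0.194%, and Turicibacter 1.06 ± 0.903% and 1.29 ± 1.11%. Parasutterella held 0.804% and 0.660% and Enterococcus 0.147% and 0.0353%, directions that turned with centred log ratios. The Lachnospiraceae NK4A136 group held 1.91% and 2.27%, Alistipes 0.716% and 0.659%, Oscillibacter 0.535% and 0.512%, Roseburia 0.475% and 0.236%, Anaeroplasma 0.0452% and 0.179%, and Escherichia-Shigella 7 and 21 reads. Each of these genera had an adjusted p of 0.999. Among 81 genera, 0 passed in edgeR, with 5 at an unadjusted p under 0.05, and 0 passed with TMM factors, DESeq2 and limma, with 7, 4 and 8 unadjusted. Muribaculaceae held 33.2 ± 2.56% and 37.4 ± 6.13%, a direction that turned with centred log ratios, Erysipelotrichaceae 9.25 ± 5.70% and 14.2 ± 4.80%, and Lachnospiraceae 9.12 ± 5.93% and 6.67 ± 4.73%, each with an adjusted p of 1. No list passed, and 0 of their members did, also when adjusted over the list alone. The smallest adjusted p of a list was 0.476, for Akkermansiaceae (exact permutation p = 0.0714) and for Bacteroidales families (39.3% against 46.4%, exact permutation p = 0.0952).

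Richness after FMT was 254 ± 47.1 in ABX and 234 ± 30 in vehicle mice (exact permutation p = 0.492), and the Shannon index 3.66 ± 0.45 and 3.88 ± 0.11 (difference -0.22, exact permutation p = 0.294). Without ABX mouse M141 the richness difference went from 19.7 to 0.936, and the Shannon difference was -0.39 (exact permutation p = 0.0159). Bray-Curtis R2 was 0.207 (exact permutation p = 0.0635), with 0.290 and p = 0.0159 without ABX mouse M141 and 0.237 and p = 0.0476 without ABX mouse M146. It was 0.156 with the Jaccard distance (exact permutation p = 0.0159) and 0.158 with the Aitchison distance (0.00794). The nearest library of 9 of the 10 after-FMT libraries was of the same pre-treatment, the exception being vehicle mouse M161, nearest to ABX mouse M146. Mean distance to the vehicle libraries before FMT was 0.745 ± 0.0143 in ABX and 0.724 ± 0.0246 in vehicle mice (exact permutation p = 0.111). Reads in ASVs of the vehicle group before FMT were 71.7 ± 4.95% and 65.9 ± 3.52% (exact permutation p = 0.0556).

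Vehicle mice received the same gavage and also changed. Unclassified Erysipelotrichaceae rose to 8.54 ± 4.10% after FMT from 0.0496 ± 0.0416%, 172-fold higher (log2 fold change 7.42, SE 2.37, adjusted p = 0.0358). Unclassified Rikenellaceae, the part of this Bacteroidales family without a genus name, rose to 2.93 ± 1.25% from 0.01 ± 0.0122%, 293-fold higher (log2 fold change 8.17, SE 2.43, adjusted p = 0.0211). The whole families changed far less. Rikenellaceae in all held 3.59 ± 1.40% after and 1.15 ± 0.860% before FMT (3.14-fold, adjusted p = 0.901). Erysipelotrichaceae in all held 14.2 ± 4.80% and 12.3 ± 11.9% (1.15-fold, adjusted p = 0.954). Parvibacter rose to 0.0542 ± 0.0310% from 0 reads (at least 12.6-fold, in 5 of 5 libraries) and unclassified Bacteroidia to 0.0577 ± 0.0750% (at least 13.4-fold, in 3 of 5), both with an adjusted p of 0.0172. Of 81 genera these 4 passed, with 10 at an unadjusted p under 0.05. The count was 7 with TMM factors (6 higher, 1 lower), 6 with DESeq2 (5 and 1), 5 with centred log ratios (4 and 1), 9 with only these groups in the fit (7 and 2), 6 with the mouse as a block (5 and 1) and 0 by the exact rank-sum test, which needs the 13 given above. Stricter identity for names called 8 and kept 2 of the 4. The adjusted p was then 0.966 for unclassified Erysipelotrichaceae (log2 fold change 0.53) and 0.0526 for unclassified Bacteroidia. Centred log ratios ended the call of unclassified Bacteroidia (0.176). The count was 0 without vehicle mouse M151, M161, M140 or M156 before FMT. The adjusted p of unclassified Rikenellaceae was then 0.0739–0.111 and that of Parvibacter and unclassified Bacteroidia 0.0694–0.0761. Unclassified Erysipelotrichaceae lost its call without any of the vehicle libraries except those of mice M155 and M161 after FMT (adjusted p = 0.0567–0.125).

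Other genera of vehicle mice did not pass. Lactobacillus held 6.34 ± 4.61% after and 0.705 ± 1.03% before FMT (adjusted p = 0.674), and Anaeroplasma 0.179 ± 0.344% and 0.00770% (0.182). Bacteroides held 5.42 ± 1.54% and 2.32 ± 0.910%, Turicibacter 1.29 ± 1.11% and 3.22 ± 1.15%, and Akkermansia 13.8 ± 4.17% and 11.4 ± 6.38% (adjusted p = 0.932 each). Dubosiella held 4.34 ± 2.03% and 9.06 ± 12.5%, a direction that turned with centred log ratios (adjusted p = 0.932). Bifidobacterium (3.32% and 2.69%), Alistipes (0.659% and 1.14%), Parasutterella (0.660% and 0.863%), Ruminococcus (0.474% and 0.299%), Roseburia (0.236% and 0.380%) and Enterococcus (0.0353% and 0.0707%) also had 0.932. So did the Lachnospiraceae NK4A136 group (2.27% and 2.77%) and Oscillibacter (0.512% and 0.608%), whose directions turned with TMM factors. Escherichia-Shigella held 21 reads against 0 (adjusted p = 0.128). Muribaculaceae held 37.4 ± 6.13% and 45.6 ± 9.0%, and Lachnospiraceae 6.67 ± 4.73% and 8.74 ± 3.75%, directions that turned with TMM factors (adjusted p = 0.942 each), and 0 families passed in edgeR. No list of 9 passed by the exact permutation test, with lactic acid bacteria at 6.38 ± 4.62% and 0.778 ± 1.04% (adjusted p = 0.179). Of 5 Bacteroidales genera 1 was higher and 2 when adjusted over the list alone. Of 6 Erysipelotrichales genera 1 was higher both ways, and of 3 Enterobacterales genera 0 passed and 1 was higher when adjusted over the list alone. Richness was 234 ± 30 and 219 ± 34.1 (exact permutation p = 0.484). The Shannon index rose to 3.88 ± 0.11 from 2.94 ± 0.33 (difference 0.94, exact permutation p = 0.00794, paired 0.063), while over genera the difference was 0.23 (p = 0.103). Bray-Curtis R2 was 0.705 (exact permutation p = 0.00794, paired 0.063). Reads in ASVs of the vehicle group before FMT were 98.1 ± 1.91% before and 65.9 ± 3.52% after. Mean distance to the vehicle libraries before FMT was 0.344 ± 0.0325 among themselves and 0.724 ± 0.0246 after. The exact permutation p of 0.00794 computed for each is no test of a change, since the ASVs and the reference come from the before libraries themselves.

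ABX mice after FMT were also set against the vehicle group before FMT, whose pre-treatment the donors shared. Unclassified Rikenellaceae was 205-fold higher (2.05 ± 1.14% against 0.01%, adjusted p = 0.0262) and unclassified Erysipelotrichaceae 115-fold higher (5.69 ± 4.57% against 0.0496%, 0.0419). As whole families, Rikenellaceae was 2.42-fold higher (2.77 ± 1.03% against 1.15 ± 0.860%, adjusted p = 0.862). Erysipelotrichaceae in all was 1.33-fold lower (9.25 ± 5.70% against 12.3 ± 11.9%, adjusted p = 0.972), a direction that turned with centred log ratios. Parvibacter (0.0385 ± 0.0167% against 0 reads, at least 8.93-fold, adjusted p = 0.0164) and unclassified Bacteroidia (0.178 ± 0.254%, in 2 of 5 libraries, at least 41.2-fold, 0.00642) were higher. Romboutsia was 62.7-fold lower (0.0102 ± 0.0159% against 0.640 ± 0.499%, 0.0470), Tuzzerella had 0 reads against 0.0197% (at least 4.45-fold lower, 0.0262), and Monoglobus 2 reads against 0.0487% (0.0419). Akkermansia held 24.4% against 11.4% (0.979) and Lactobacillus 6.47% against 0.705% (0.428). Turicibacter held 1.06% against 3.22% (0.814), Anaeroplasma 0.0452% against 0.00770% (0.503), and Escherichia-Shigella 7 reads against 0 (0.358). Bacteroides (3.31% against 2.32%), Bifidobacterium (1.78% against 2.69%) and Ruminococcus (0.175% against 0.299%) had an adjusted p of 0.979. Dubosiella held 2.50% against 9.06% (0.748), a direction that turned with centred log ratios, as did those of Roseburia (0.475% against 0.380%) and Enterococcus (0.147% against 0.0707%). The directions of the Lachnospiraceae NK4A136 group (1.91% against 2.77%), Alistipes (0.716% against 1.14%) and Oscillibacter (0.535% against 0.608%) turned with TMM factors, and that of Parasutterella (0.804% against 0.863%) with TMM factors and DESeq2 (0.979 for these 6). Muribaculaceae held 33.2 ± 2.56% against 45.6 ± 9.0% (0.972), a direction that turned with centred log ratios. This comparison shares its vehicle libraries with the one above, and the overlap of their genera was not tested.

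Of 81 genera, 7 passed against the vehicle group before FMT (4 higher, 3 lower), with 12 at an unadjusted p under 0.05. The count was 8 with TMM factors (5 and 3), 8 with DESeq2 (6 and 2), 10 with centred log ratios (5 and 5) and 0 by the exact rank-sum test, which needs 13. Tuzzerella had an adjusted p of 0.105 with DESeq2, and unclassified Bacteroidia 0.151 on centred log ratios and 0.0648 with only these 2 groups in the fit. With no filter Monoglobus and unclassified Erysipelotrichaceae had 0.0572 and Romboutsia 0.0638. The count was 1 without vehicle mouse M151 or M140, 2 without vehicle mouse M161 or ABX mouse M141, 3 without vehicle mouse M156 or ABX mouse M139, M146 or M149, and 4 without ABX mouse M159. Unclassified Erysipelotrichaceae and Romboutsia each lost the call without any of the 10 libraries (adjusted p = 0.0534–0.1 and 0.0506–0.120), and only unclassified Bacteroidia of the 7 kept it in each case. Unclassified Rikenellaceae lost it without 5 libraries (0.0603–0.0868), Parvibacter without 3 (0.0533–0.0809), Tuzzerella without 7 (0.0506–0.0868) and Monoglobus without 8 (0.0652–0.120). With stricter identity for names, unclassified Erysipelotrichaceae had a log2 fold change of -2.15 (SE 1.71, adjusted p = 0.551). No list of 10 passed by the exact permutation test, with lactic acid bacteria at an adjusted p of 0.0794, Akkermansiaceae at 0.159 and Bacteroidales at 0.212. Of 29 Clostridia genera 1 was lower, of 5 Bacteroidales 1 higher and of 6 Erysipelotrichales 1 higher, also when adjusted over the list alone. Richness was 254 against 219 (exact permutation p = 0.206). The Shannon index was higher by 0.72 (exact permutation p = 0.0317), and by 0.16 over genera (p = 0.317). Its p was 0.0556–0.0635 without ABX mouse M141, M159 or M139 or vehicle mouse M151, M155 or M156. Bray-Curtis R2 was 0.695 (exact permutation p = 0.00794).

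Whether the change from before to after FMT differed between the pre-treatment groups was tested as an interaction. The log2 change of unclassified Enterobacteriaceae was lower in ABX than in vehicle mice (difference -12.11, SE 3.16, adjusted p = 0.0107), with a change of -69.9 ± 39.5 percentage points in ABX and 0.0111 ± 0.0177 in vehicle mice. Romboutsia (9.95, SE 2.82, 0.0178), Ruminococcus (9.22, 0.0194) and the Eubacterium nodatum group (8.88, 0.0194) had a higher log2 change in ABX mice. The ABX libraries before FMT held 2, 0 and 0 of their reads, so these log2 values are no bounds. In percentage points the change of Romboutsia was 0.00963 ± 0.0164 in ABX and -0.632 ± 0.498 in vehicle mice, that of Ruminococcus 0.175 ± 0.229 and 0.175 ± 0.322, and that of the Eubacterium nodatum group 0.0314 ± 0.0120 and -0.0827 ± 0.0890. Of 81 genera these 4 passed, with 17 at an unadjusted p under 0.05. The count was 4 with TMM factors, 15 with DESeq2 (9 and 6), 33 with centred log ratios (19 and 14, with Ruminococcus at a log2 difference of 0.08, adjusted p = 0.969, and the Eubacterium nodatum group at 2.92, 0.0910), 41 with the mouse as a block (40 and 1) and 0 by the exact rank-sum test, which needs 13. It was 54 without ABX mouse M149, 2 without ABX mouse M146 and 0 without vehicle mouse M155 or M156. Richness changed by 177 ± 171 ASVs within ABX mice and 14.7 ± 42.7 within vehicle mice (difference 163, exact permutation p = 0.0556). The ABX mice changed by 223, 316, 218 and 251, and mouse M149 by -120. Without mouse M149 the difference was 237 (exact permutation p = 0.00794). No list of 10 passed, the largest difference being -69.7 percentage points for Enterobacterales families (exact permutation, adjusted p = 0.0794), with 20.2 for Akkermansiaceae (0.0794) and 32.9 for Bacteroidales families (0.106).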

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

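All tests of this part were chosen after the results were seen, except that on reagent DNA and that on reads within 2 edits of a vehicle ASV. The outlier values use the Dixon ratio for 5 libraries. Among 56 sets of 5 libraries, 19 held an outlier, 11 of them in the library of mouse M149 before FMT. Chance gives about 1 in 20 sets of independent normal values. These sets are related measures of the same libraries, some with shares of 0, so the counts cannot be judged against that rate. Of the 19, 16 are given here, and the other 3 stayed under 0.05% of reads in every library. Among 114 sets of named genera, 45 held an outlier, 22 of them in that library.

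The ABX library of mouse M149 before FMT held 326 ASVs (other ABX libraries 12.9–15.8), a Shannon index of 4.33 (0.88–1.14), a mean distance to the vehicle group before FMT of 0.766 (0.991 in each other library) and 65.4% of reads in ASVs of that group (5.41–19.5%). Its shares were 28.0% Clostridia families (others 0–0.00720%), 45.1% Bacteroidales families (0.00407–0.0118%), 9.56% Akkermansiaceae (0–0.00908%), 0.126% Enterobacterales families (80.5–94.6%), 10.9% lactic acid bacteria (0.00407–0.0515%), 0.0595% Bifidobacteriaceae (0 in the others) and 1.42% Erysipelotrichales families (0–0.0122%).

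An after-FMT pellet, DNA or library under this label would fit its Bray-Curtis distance of 0.0681 to mouse M141 after FMT. Different after-FMT libraries lay at least 0.199 apart, and sampling alone gave at most 0.0308 in 100 simulations. The 4 other ABX libraries before FMT lay 0.0275–0.141 from each other, so a distance this low also occurs between different mice. The lowest distance of this library to a vehicle library before FMT was 0.733, above the 0.528 of the farthest after-FMT library, so it lay nearer to the after-FMT libraries. Vehicle libraries after FMT also lay 0.594–0.792 from the vehicle libraries before FMT. A community that the antibiotics left in place is therefore not excluded, as mouse M149 has no library from before treatment to compare. Enterobacteriaceae made up 0.126% of reads, within the range of after-FMT libraries. This argues against after-FMT reads added to a library that kept a large share of its own depleted community. Carry-over that made up nearly all reads cannot be told apart by this share. Distances to the other ABX libraries before FMT were 0.998–0.999, and the distance to the library of mouse M149 after FMT was 0.465. Where such a swap may have happened was not tested.

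Both groups gained 64 ASVs after FMT that were not ASVs of the vehicle group before it, of 123 gained by ABX and 84 by vehicle mice. Sequence errors or trimming of vehicle ASVs are excluded as the source of most, as the median distance to the nearest vehicle ASV was 28 edits with free ends (quartiles 7 and 34). For the 11 ASVs within 2 edits, with 14.9% of the reads of the 64, errors or read processing could not be excluded. ASVs under the detection limit before FMT could not be excluded either, as 21.9% had a read in a vehicle library before FMT, and the bound for this test was moved to 0 after that value was seen. Transfer was not tested, since the overlap of the lists was 3.20 times that of independent lists among all 517 ASVs read after FMT and 1.05 times among the 170 frequent enough to enter a list.

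Organelle reads of the 21-day ABX libraries held chloroplast and mitochondrial sequences in ratios that differed 1.08-fold at most, which is consistent with 1 source such as food. Reagent DNA shared by all libraries cannot be told apart from it, with 13.4% of these reads in ASVs that a vehicle library also holds. A difference in library total cannot be told apart from treatment, since every ABX total lay below every vehicle total. Among the 3 ABX libraries the totals of 9387, 19125 and 21771 reads went with 71.2, 79.7 and 24.7% organelle reads, and the bound for this test was rewritten after these values were seen.

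The library of vehicle mouse M161 after FMT held 23.5% Clostridia families against 6.80–8.92% in the others. It held 21.1% Akkermansiaceae against 10.5–12.6%. The library of vehicle mouse M155 before FMT held 22.6% Akkermansiaceae against 6.94–10.5%. ABX mouse M146 after FMT held 2.04% Enterobacterales families against 0.0445–0.115%. Vehicle mouse M161 before FMT held 2.62% lactic acid bacteria against 0.111–0.528%. The log2 change from before to after FMT differed between pre-treatments in 4 genera, and in 0 without vehicle mouse M155 or M156.

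Libraries were also split in other ways, and the genera called were counted. At 21 days the 10 splits are too few for a share under 0.05, with 4 genera in the real 1 and 0 at most in the others (1 of 10 splits with as many). For ABX against vehicle before FMT, 1 of 100 splits called as many as the real 20, with 16 at most in the others. For ABX after against before FMT, 2 of 100 splits called at least 8, with 22 at most, and among splits that part each mouse's libraries 2 of 16 did. For vehicle after against before FMT it was 1 of 100 (1 of 16 that part the pairs), with 1 genus at most in the others. For ABX after against vehicle before it was 1 of 100, with 1 at most, and for ABX against vehicle after FMT, where 0 genera passed, 100 of 100. For the difference of changes 4 of 100 splits called at least 4, with 12 at most. Why splits gave 22 and 12 genera was not tested, and 60 and 54 genera passed in these 2 comparisons without mouse M149.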

How the results depend on the processing

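Tests with primers removed, with stricter identity, without mice M149 and M141, and of lists without either library were chosen after the results were seen. Of 170 alternative values of the main results, 118 kept their call, 9 weakened, 4 strengthened, 39 moved a count and 0 turned sign; of 274 with 1 library left out the numbers were 221, 23, 5, 25 and 0. For named genera and lists, 962 of 1095 alternatives and 996 of 1116 with 1 library left out kept their call, 8 and 3 turned sign with a call, and 36 and 37 turned sign with no call. Families and phyla were not refitted with libraries left out. The cause was not tested for any result that changed. Counts of 0 by rank-sum weigh little, since at least 13 of 81 genera have to reach its smallest p before any passes. Day as a block kept 17 of the 20 calls before FMT, without Parvibacter and unclassified Bacteroidia, which it did not test, and unclassified Rikenellaceae. Mouse as a block kept 7 of 8 for ABX mice, 4 of 4 for vehicle mice and 4 of 4 for the difference of changes, and both blocks added calls.

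Diversity results changed as follows. The Shannon difference over genera was -1.31 for ABX against vehicle before FMT, 0.23 for vehicle after against before and 0.16 for ABX after against vehicle before. With mice paired, richness (177), Shannon (1.98), R2 (0.589), distance (-0.201) and reads in vehicle ASVs (48.7) of ABX after against before FMT, and Shannon (0.94) and R2 (0.705) of vehicle mice, kept their values and lost the call. R2 of ABX against vehicle after FMT was 0.156 with Jaccard and 0.158 with Aitchison distance. The richness difference of changes was 216 without mice M149 and M141. Taxon lists past the threshold were 7 before FMT and 7 for ABX after against before without mouse M149. With mice paired they were 0 for ABX after against before, where none could pass.

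Genus counts moved as follows. At 21 days they were 34 with TMM, 30 with DESeq2, 41 with centred log ratios, 16 with filterByExpr, 101 for ASVs, 31 for families and 0 with organelle reads removed. Before FMT they were 46 with centred log ratios, 11 with only 2 groups, 73 for ASVs, 11 for families and 53 with day as a block. For ABX after against before they were 14 with DESeq2, 50 with centred log ratios, 0 with only 2 groups, 3 for families, 0 by rank-sum, 47 with mouse as a block and 60 without mouse M149 before and M141 after FMT. For vehicle mice they were 7 with TMM, 9 with only 2 groups, 67 for ASVs, 0 for families, 8 with stricter identity and 0 by rank-sum. For ABX after against vehicle before they were 4 with no filter, 77 for ASVs, 2 for families, 11 with stricter identity and 0 by rank-sum. For the difference of changes they were 15 with DESeq2, 33 with centred log ratios, 52 for ASVs, 41 with mouse as a block, 0 by rank-sum and 54 without mice M149 and M141.

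Leaving out 1 library, results whose call changed had these ranges. Richness before FMT was -205 to -127 and Shannon -1.92 to -1.06. Richness of ABX after against before was 158.7 to 240 and Shannon 1.78 to 2.64. Shannon of ABX against vehicle after FMT was -0.39 to -0.11 and R2 0.178 to 0.290. Shannon of ABX after against vehicle before was 0.55 to 0.83, and the richness difference of changes 128 to 237. Genera were 4 to 60 at 21 days, 13 to 61 before FMT, 6 to 60 for ABX after against before, 0 to 4 for vehicle mice, 1 to 5 for ABX after against vehicle before and 0 to 54 for the difference of changes.

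These signs turned. Turicibacter at 21 days was 10.62 without vehicle library 3 (range -4.17 to 10.62). Before FMT, unclassified Rikenellaceae was -2.44 with day as a block and -5.79 without mouse M149 (range -5.79 to 7.13), Lactobacillus -7.36 and -8.45 (range -8.45 to 3.13), and unclassified Christensenellaceae 0.19 with centred log ratios. For ABX after against before, centred log ratios gave -1.24 for the Eubacterium brachy group, -1.47 for Christensenellaceae, -3.12 for Escherichia-Shigella and -4.88 for Enterococcus. Unclassified Erysipelotrichaceae was -2.15 with stricter identity for ABX after against vehicle before.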

Other observations

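The tests of this part were chosen after the result was seen. Of the 259 ASVs of the vehicle group before FMT, 163 (62.9%) were found in vehicle mice after FMT, 61.4% in ABX mice after FMT and 10 (3.86%) in ABX mice before it, where found means at least 3 reads in at least 2 libraries. That rule leaves out ASVs of mouse M149 alone, whose library before FMT held 152 of the 259 with at least 3 reads. The 64 ASVs gained by both groups made up 30.8 ± 4.62% of vehicle and 24.8 ± 3.63% of ABX reads after FMT, against 0.0726 ± 0.0851% of vehicle reads and 5.93 ± 13.3% of ABX reads before, with 29.7% in mouse M149. By family, 33 were Muribaculaceae (23.4 ± 4.32% of vehicle and 18.4 ± 1.18% of ABX reads after FMT), 2 Bacteroidaceae (3.07 ± 0.897% and 1.82 ± 0.886%), 3 Lactobacillaceae (1.25 ± 1.48% and 1.96 ± 2.34%) and 9 Lachnospiraceae (0.965 ± 0.504% and 1.02 ± 1.22%). Of these ASVs, 49 had no read in any library before FMT but that of mouse M149. Another 61 ASVs of the vehicle group, with 4.06 ± 2.15% of its reads, were found in neither group after FMT, 21 of them Lachnospiraceae and 10 Ruminococcaceae.

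The leading pair of Enterobacteriaceae ASVs of ABX mice before FMT differ by 1 edit and together made up 80.4–94.4% of reads in 4 libraries. Their ratio was 1.55–1.58 in these libraries, a 1.02-fold spread, which is consistent with 2 copies of the gene in 1 organism. A genome or full-length 16S sequence of an isolate would test this.

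Before FMT, 20 genera passed with the library of mouse M149 and 61 without it. Of the 20, 18 stayed called without it, unclassified Rikenellaceae with the opposite sign. If it may be an after-FMT library, as its distance of 0.0681 to mouse M141 after FMT could mean, the record of that tube or a new library from the pellet would tell.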
